A study of Gallus gallus with 2 samples.

How the data were processed

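Poly(A) RNA of DT40 cells was sequenced in paired-end libraries, 1 of wild-type and 1 of SRSF10-deficient cells, per the labels' protocols. TopHat2 2.0.6, Cufflinks and the galGal4 build are named in the submitters' processing notes. The program that called and counted splicing events, and the test behind the authors' p-values, are not given in the sources used here. The table deposited by the authors gives, for each event, a gene name, a position, an event type and, per library, the read counts that support exclusion and inclusion, per the file headers. These deposited values are raw read counts with no visible normalization. The authors' adjusted p-value is listed per event in the deposited table, is 1 in 53.2% of events, and was not recovered by Fisher's exact test on the listed counts.

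The table held 10652 rows. Of these, 10376 had 2 numbers per library, and 276 had 3 or more numbers whose order the header does not explain, which were left out of the tests. After 63 repeated rows were removed, 10313 events under 5409 gene names remained. In the full table, 168 rows named chromosomes without the usual prefix. There were 506 unnamed assembled loci. Names were matched to current symbols with the gene table of the GRCg7b assembly, which was used for names and synonyms only, and 4421 names (81.7%) matched. Spreadsheet dates in 5 names were read as septins. Coordinates are as listed by the authors. Cassette exon length was taken as end minus start plus 1, a quantity divisible by 3 in 56.9% of cassette exons, against 21.7% without the added base. For alternative sites, end minus start was taken as the distance between the sites.

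An inclusion level in percent was computed from the deposited counts. It takes no account of the larger number of junctions that can support inclusion of a cassette exon. Each event with at least 20 reads in each library was tested with a two-sided Fisher's exact test on its exclusion and inclusion reads. P-values were adjusted by the Benjamini-Hochberg method over all tested events, and an event was called changed at an adjusted p under 0.05 and a difference of at least 10 percentage points. The 6089 tested events had a median of 95 reads in the wild-type and 98 reads in the deficient library, with quartiles of 49 and 222, and of 50 and 221. Without replicates, the test treats reads as independent and takes no account of variation between cultures or library preparations. Both exons of a mutually exclusive pair can be listed as separate rows, and undefined events have nearly equal numbers in many rows, so their 2 counts need not be competing isoforms. Intervals are 95% Clopper-Pearson intervals, and 0 inclusion reads are given with the limit that 3 counts allow.

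The rule for named events was fixed before the data were examined. It took the 10 widest cassette exon changes in each direction, the 3 widest of every other type in each direction, up to 4 changed members of each of 17 gene lists, and SRSF10. As applied, it kept 1 changed event per gene within each event type and direction, so a gene could be named for more than 1 event. Some events that meet the rule are not reported here. The lists were also fixed before the data were examined, and each was compared with all other tested genes by Fisher's exact test with Benjamini-Hochberg adjustment over the lists. Lists were further compared with 10000 random lists matched on number of tested events and reads. Exon length was compared by permuting medians (100000 resamples) and divisibility by 3 by Fisher's exact test. Unchanged exons had an adjusted p of at least 0.05 and a difference under 5 points.

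Alternatives set in advance changed the minimum reads (10 or 50), the minimum difference (0 or 20 points), the adjusted p (0.01), the weight of reads (divided by 2), the events per gene (1), the weight of cassette inclusion reads (halved) and the test (the authors' adjusted p). Chosen after seeing the data were a division of each chi-square by the median inflation of its event type (held at 1 for undefined events, whose inflation was 0.162, so that their 8 calls among the 56 kept were not tested by it), 1 row per position, a narrower set of event types, the matched lists and unchanged exons of intermediate inclusion. Inflation was the median chi-square over its expected median, for events with expected counts of at least 5. Sequence features of exons were not analysed here, since no galGal4 sequence was used here. The calling step was tested on simulated data for the comparison of the 2 libraries, with 200 of 6089 events changed. It recovered 44.5% of changes of 15 points, with 1 false call, and 78.5% of changes of 30 points, with 3 false calls. With no simulated change it made 0 false calls. The simulation held counting noise only, not the larger spread between the real libraries, so these numbers do not give the false calls among the events reported. Python 3.11.15, SciPy 1.17.1, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 were used.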

Results

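Splicing was measured by RNA sequencing in chicken DT40 cells, a B-lymphoblast line derived from the bursa of Fabricius. The cells either carried the wild-type genotype or lacked SRSF10, an RNA-binding splicing factor of the serine/arginine-rich (SR) family. There was 1 library per genotype, so no value below has a replicate check, and every test compares 2 libraries, not 2 genotypes. The deposited table listed read counts for the exclusion and the inclusion of 10313 splicing events under 5409 gene names, with positions in the galGal4 build. The listed reads summed to 2047625 in the wild-type library and 2022343 in the SRSF10-deficient library, with a median of 38 and 40 reads per event. Total sequencing depth was not given in the sources used here. SRSF10 itself had 0 rows in the table, so the genotype label of the deficient library could not be checked with its target gene. Inclusion levels are inclusion reads as a percent of inclusion plus exclusion reads, and differences are deficient minus wild type in percentage points. All intervals are 95% Clopper-Pearson intervals, and intervals and limits cover counting error only.

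The first comparison asked which cassette exons, the exons that are either kept or skipped as a whole, were spliced differently without SRSF10. Exons of PHF20L1, IMPDH2, ARHGAP17 and CLASP2 were skipped more often in the SRSF10-deficient library, while exons of EPRS, KIFC1 and PTPRC were included more often. Of 2175 cassette exons with at least 20 reads in each library, 132 (6.07%, 5.10 to 7.16) passed an adjusted p of 0.05 by Fisher's exact test with a difference of at least 10 points. Inclusion was higher in the deficient library for 69 of them and lower for 63, a higher share of 52.3% (43.4 to 61.0). The median difference was 20.3 points among the exons that rose and -19.7 points among those that fell. The spread between the libraries exceeded counting noise, in that the median chi-square of cassette exons was 3.97 times the value that counting noise gives. With each chi-square divided by that factor, a correction chosen after seeing the data, 12 of the 132 exons kept the call, 6 higher and 6 lower. The factor was 2.75 for exons below the median depth and 5.35 for the others, so the correction by 3.97 was too strict for shallow exons and too mild for deep ones, and the kept and lost calls below depend on that choice.

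**Figure D1:**
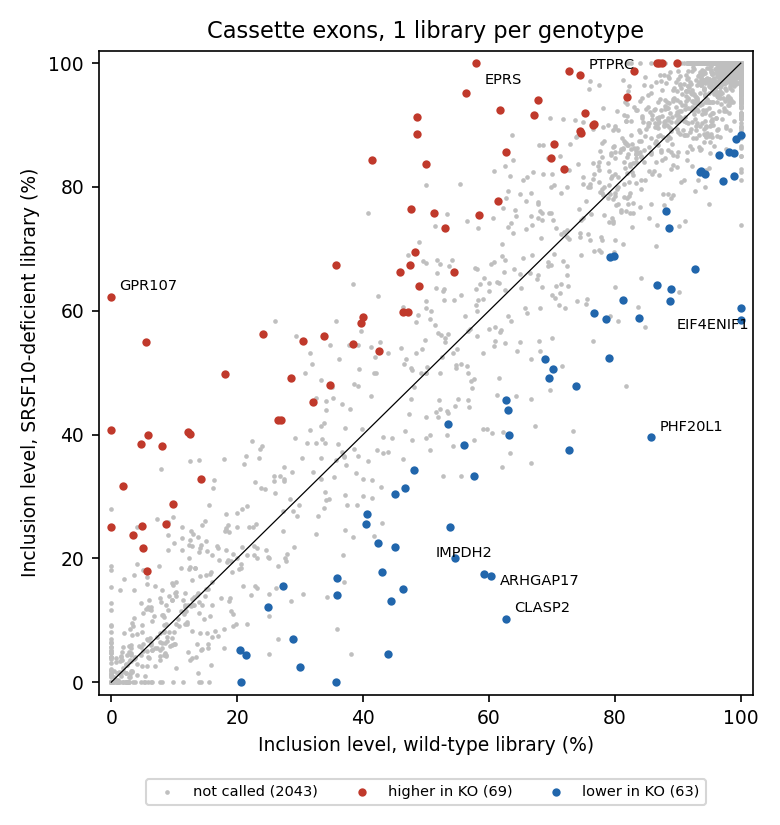
Inclusion level (%) of 2175 cassette exons in the wild-type library (x axis) and the SRSF10-deficient library (y axis), 1 point per exon, with the line of equal inclusion. Exons called higher (69, red) and lower (63, blue) in the deficient library lie on both sides of the line, and 2043 exons were not called (grey).

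Among the exons that were skipped more often, a 219 nt exon of PHF20L1, a reader of methylated lysine (chromosome 2, 141308382 to 141308600), fell from 85.8% inclusion (81.1 to 89.6; 281 reads) to 39.6% (33.2 to 46.4; 222 reads), with an adjusted p of 3.73e-25. A 72 nt exon of IMPDH2, an enzyme of guanine nucleotide synthesis (chromosome 12, 11622485 to 11622556), fell from 59.2% (55.7 to 62.6; 789 reads) to 17.5% (14.5 to 20.8; 589 reads), with an adjusted p of 4.22e-54. In ARHGAP17, a GTPase-activating protein, a 48 nt exon (chromosome 14, 6567229 to 6567276) fell from 60.4% (54.3 to 66.2; 275 reads) to 17.1% (10.8 to 25.2; 117 reads). The adjusted p for ARHGAP17 was 1.43e-13. The difference was widest for a 24 nt exon of CLASP2, a microtubule plus-end protein (chromosome 2, 45303179 to 45303202), at 62.7% (53.3 to 71.4; 118 reads) and 10.3% (2.87 to 24.2; 39 reads). CLASP2 had an adjusted p of 5.50e-07, but of 0.22 with the correction for the spread above counting noise. The other 6 of the 10 widest decreases were in HMGXB4 (100% to 58.5%), EIF4ENIF1, a carrier of the cap-binding protein (100% to 60.5%), MAP4K5 (44.0% to 4.55%), MED21, a Mediator subunit (35.7% to 0%), LGALS8, a galectin (72.7% to 37.5%), and TBC1D22A (54.5% to 20%). The MED21 value rests on 0 of 39 reads, which allows an inclusion of up to 7.69%. None of these 6 kept the call with the correction.

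Among the exons that were included more often, a 79 nt exon of EPRS, the glutamyl-prolyl-tRNA synthetase (chromosome 3, 18200072 to 18200150), rose from 57.9% (52.0 to 63.7; 290 reads) to 100% (98.3 to 100; 214 reads), with an adjusted p of 3.11e-33. A 39 nt exon of KIFC1, a minus-end-directed kinesin (chromosome 16, 228615 to 228653), rose from 48.6% (40.04 to 57.2; 140 reads) to 88.5% (85.4 to 91.1; 521 reads), with an adjusted p of 7.30e-20. For GPR107, a membrane protein of the Golgi, a 200 nt exon (chromosome 17, 5827330 to 5827529) had 0 of 21 reads in the wild-type library, which allows up to 14.3%. It reached 62.3% (47.9 to 75.2) over 53 reads in the deficient library, with an adjusted p of 1.25e-05, and of 0.396 with the correction. The other 7 of the 10 widest increases were in PIP5K1B, a phosphoinositide kinase (5.56% to 55.0%), MAT1A, a methionine adenosyltransferase (41.4% to 84.4%), TTC21B, a cilium transport protein (48.6% to 91.3%), BANP (0% to 40.7%), UBN1, of a histone chaperone complex (56.4% to 95.1%), PPFIA1 (5.88% to 40%), and TUBGCP5, of the gamma-tubulin complex (4.65% to 38.5%). None of these 7 kept the call with the correction, and the wild-type BANP value rests on 0 of 27 reads, which allows up to 11.1%.

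**Figure D2:**
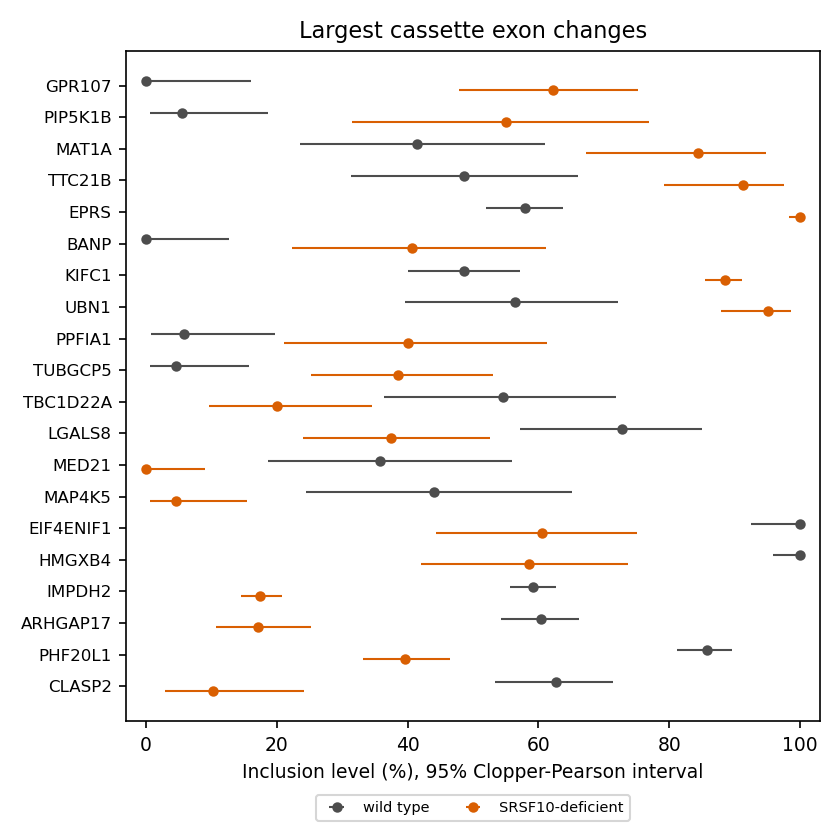
Inclusion level (%, x axis) in the wild-type (grey) and SRSF10-deficient (orange) library of the 10 cassette exons with the largest increase (top) and the 10 with the largest decrease (bottom). Bars are 95% Clopper-Pearson intervals for counting error in 1 library each, and they are wide for exons with few reads, such as PIP5K1B (36 and 20 reads).

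The second comparison set the event types side by side. Over all types, 6089 events in 3456 genes were tested, and 286 events in 243 genes changed, 151 with higher and 135 with lower inclusion in the deficient library. Besides the 132 cassette exons, these were 46 of 1004 alternative 3' splice sites (27 higher, 19 lower), 37 of 878 alternative 5' splice sites (18 higher, 19 lower) and 18 of 397 retained introns (11 higher, 7 lower). Rows of mutually exclusive exons changed in 42 of 90 cases (23 higher, 19 lower), and events with no defined type changed in 11 of 1545 (3 higher, 8 lower). The planned Fisher's exact comparison of directions between types found no detectable difference, but says little, since inclusion is not defined for competing sites and 8 of the 42 changed mutually exclusive rows mirror another. Cassette exons changed more often than the other types together (Fisher's exact adjusted p = 0.000468), but not than the other 4 defined types together, with 143 of 2369 (6.04%; Fisher's exact p = 1.00, a comparison added after seeing the data). That equal share hinges on the mutually exclusive rows. The shares were lower for alternative 3' sites (4.58%), alternative 5' sites (4.21%) and retained introns (4.53%), and cassette exons were not tested against these 3 types together. Changes were also more frequent in mutually exclusive rows (Fisher's exact adjusted p = 5.89e-32) and less frequent in undefined events (Fisher's exact adjusted p = 6.85e-23). Those shares cannot be read as rates of regulation, since the spread above counting noise was 13.7 times for mutually exclusive rows and 0.162 times for undefined events. The authors' deposited table gave an adjusted p under 0.05 to 172 of the 10313 listed events (152 of the tested events), of which 130 were cassette exons (70 higher, 60 lower). Of the 286 changed events, 98 also had an adjusted p under 0.05 in the authors' deposited table.

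**Figure D3:**
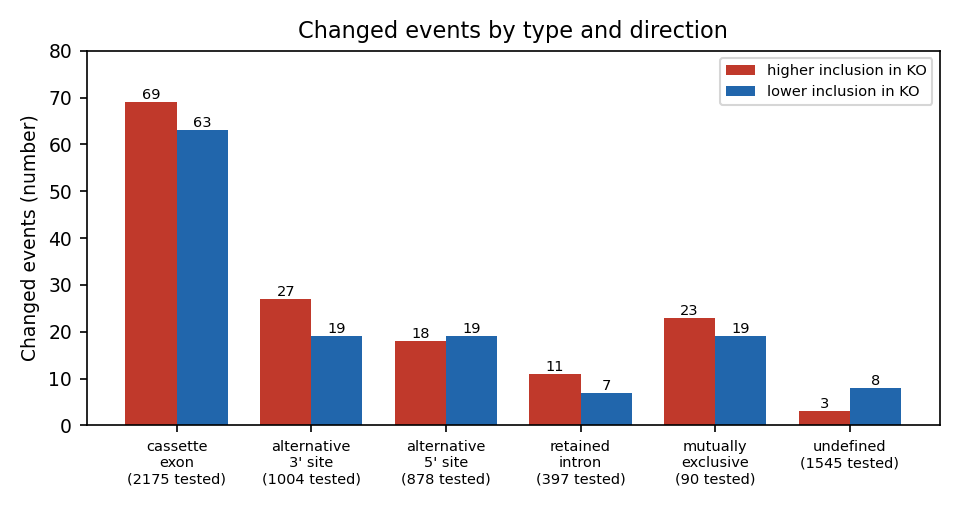
Number of changed events (y axis) per event type, with higher (red) or lower (blue) inclusion in the SRSF10-deficient library, and the number tested under each name. Cassette exons had the most changed events (69 higher, 63 lower).

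Among alternative 3' splice sites, BCLAF1, an SR-related protein linked to SRSF10 in other work, had the widest increase. At a 525 nt region (chromosome 3, 54492761 to 54493286), inclusion rose from 19.6% (13.3 to 27.2; 138 reads) to 92.9% (85.8 to 97.1; 98 reads), with an adjusted p of 9.00e-29, and of 1.97e-12 with the correction. The table also lists the position under LOC100858086, at 15.8% and 88.9%. Wide changes were further seen at 3' sites of SGTA, a co-chaperone (0% to 64.3%), BPTF, a nucleosome remodelling factor (61.2% to 0%), EPB41, a membrane skeleton protein (38.7% to 0%), and UNC5B, a netrin receptor (42.9% to 0%). The unnamed locus XLOC_020325 had 7.55% and 70.0%, over 53 and 20 reads. The BPTF value of 0 comes from 28 reads, which allows up to 10.7%, that of EPB41 from 99 reads (up to 3.03%), that of UNC5B from 32 reads (up to 9.38%), and that of SGTA from 21 reads (up to 14.3%). Of these genes, UNC5B lost its call with the correction.

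Among alternative 5' splice sites, MKS1, a protein of the ciliary transition zone, switched completely. On an unlocalised scaffold of chromosome 19 (12727 to 13238), 0 of 254 reads supported inclusion in the wild-type library, which allows up to 1.18%, and 249 of 249 did in the deficient library (98.5 to 100). The adjusted p for MKS1 was 3.35e-147. KIFC1 rose from 0 of 72 reads (up to 4.17%) to 84.0% (79.8 to 87.5) at a 39 nt region (chromosome 16, 289927 to 289966), whose exclusion reads, 72 and 60, equal those of the KIFC1 cassette exon, so these are not independent events. HMGXB4 rose from 0% (up to 13.6%) to 81.0% over 22 and 21 reads, and its 17 inclusion reads in the deficient library equal the exclusion reads of the HMGXB4 cassette exon, so these events are not independent either. BAP1, a deubiquitinase, fell from 60.5% (53.1 to 67.6) to 19.9% (13.5 to 27.6), with an adjusted p of 2.02e-11. ZC3H7B fell from 69.2% to 21.4%, and CTSB, the protease cathepsin B, fell from 98.0% to 60.5% at sites 2 nt apart, and both lost their calls with the correction (adjusted p of 0.492 and 0.0548). The table defines inclusion by exons only, so it does not state which of 2 competing sites counts as inclusion.

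At retained introns, listed inclusion rose in CWF19L2 (68.3% to 100%) and LOC693249 (72.0% to 94.8%), and fell in MYCBPAP (71.8% to 28.8%), C1H12orf35 (52.8% to 17.5%) and UBE2E3 (100% to 69.0%). What counts as inclusion of an intron is not stated, so the direction of retention is not known. None of these 5 introns kept its call with the correction. Of all 18 changed retained introns, 3 kept theirs, among them those of IDI1 (36.2% to 57.8%) and TMEM115 (83.9% to 99.8%). Mutually exclusive rows with the widest changes lay in TUBB, a beta-tubulin (0% to 94.2%), SLC38A7 (0% to 66.9%), HNRNPA2B1, an RNA-binding protein (100% to 5.99%), VIPAS39 (90.2% to 0%), and B-G, a gene family of the major histocompatibility region, with 1 row at 0% and 52.7% and another at 100% and 0%. The values of 0 allow up to 11.5% for TUBB, 5.88% for SLC38A7, 12% for VIPAS39, and 11.5% and 10% for the B-G rows. Of these mutually exclusive rows, that of HNRNPA2B1 kept its call with the correction. Undefined events changed in EIF2C1, the Argonaute gene now named AGO1 (15.5% to 37.4%), LOC427773 (84.8% to 100%), IGLL1, an immunoglobulin light chain gene (55.9% to 4.65%), SREK1, an SR-related splicing regulator (95.05% to 56.6%), and R3HDM1 (40.5% to 19.5%). The correction left the chi-square of undefined events as it was, since their spread was below counting noise, so it does not test these calls. P-values were adjusted anew over all events, and with that the LOC427773 event lost its call (adjusted p of 0.103).

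The third comparison counted changed genes in 17 gene lists, against all other genes with a tested event. The cytoskeleton list stood out, with 12 of 59 tested genes changed (20.3%, 11.0 to 32.8) against 6.80% of other genes. Of these, 9 had lower inclusion in the deficient library at their widest event and 3 had higher inclusion, and 12 changed when adjusted over the list alone. That split counts EPB41, KLC1 and a septin gene at competing sites and ACTN4 in a mutually exclusive row, where direction is not defined. Directions in the lists below count such events in the same way. The 12 genes included ARHGAP17 and EPB41, given above, KLC1, a kinesin light chain (71.4% to 37.8%), and SPTAN1, a spectrin (44.4% to 13.0%). With the correction KLC1 and SPTAN1 lost their calls, and ARHGAP17 and EPB41 kept theirs. The other 8, named after their values were seen, were DIAPH1, ADD1, MAP4, ABI2 and ABI1, with lower inclusion, and ACTN4, DCTN1 and a septin gene, with higher inclusion. DIAPH1 is the authors' listed name, which was matched to the current symbol DIAPH2. The adjusted p for the list was 0.0108 by Fisher's exact test over genes, which are not replicates, as for all lists below. The count exceeded that of most random lists matched on events and reads (one-sided p over the random lists = 0.0104, not adjusted over the 17 lists). The call was lost with cassette exons alone (21.6% against 7.35%, exact adjusted p = 0.0948), with differences of at least 20 points (10.2% against 3.77%, 0.165) and with the correction for spread (3.39% against 1.38%, 0.576). In each of these settings fewer genes were called, and the share stayed higher in the list than in other genes.

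The list of hnRNPs and other RNA-binding regulators had 7 of 35 genes changed (3 higher, 4 lower; 7 adjusted over the list alone), with an adjusted p of 0.0812. Its widest change was that of HNRNPA2B1, given above, which kept its call with the correction. Its members also included RBM33 (32.2% to 50.3%), TIAL1 (74.8% to 57.6%) and PTBP2, the neuronal homologue of the polypyrimidine tract-binding protein (98.9% to 81.8%), and these 3 lost their calls with the correction (adjusted p of 0.396 or more). Among SR proteins, 3 of 19 changed (2 higher, 1 lower; 3 adjusted over the list alone; exact adjusted p = 0.410), namely BCLAF1, SREK1 and SRSF6 (26.9% to 64.3%, at 3' sites 2 nt apart). In the spliceosome core, 3 of 24 changed (1 higher, 2 lower; 3 adjusted over the list alone; exact adjusted p = 0.501). U2SURP fell from 63.0% to 43.9%, and PUF60 rose from 36.4% to 48.3%. CPSF6, a 3' end processing factor, rose from 34.7% to 48.0%, as the 1 changed gene of 31 in the list of RNA export, 3' end processing and decay (1 adjusted over the list alone; exact adjusted p = 0.943). SRSF6, U2SURP, PUF60 and CPSF6 lost their calls with the correction (adjusted p of 0.315 or more), and BCLAF1 kept its call. The direction is not defined for RBM33, TIAL1, BCLAF1, SRSF6 and PUF60, at competing sites, or for HNRNPA2B1, in a mutually exclusive row. SREK1 changed in an event with no defined type. BCLAF1 was also the 1 tested gene of the list linked to SRSF10 in other work (1 adjusted over the list alone; exact adjusted p = 0.299).

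B-cell receptor and lymphocyte signalling genes changed in 5 of 43 cases (4 higher, 1 lower; 5 adjusted over the list alone; exact adjusted p = 0.501). A 138 nt exon of PTPRC, which encodes the leukocyte phosphatase CD45 (chromosome 8, 2045308 to 2045445), rose from 74.5% (71.6 to 77.2; 956 reads) to 98.0% (97.1 to 98.7; 1411 reads). Its adjusted p was 1.46e-69, and 1.28e-16 with the correction. PPP3CB, a calcineurin subunit, rose from 70.3% to 87.0%, and IKZF1, the transcription factor Ikaros, fell from 48.1% to 34.3%, and both lost their calls with the correction (adjusted p of 0.267 and 0.729). Chromatin regulators changed in 9 of 76 genes (5 higher, 4 lower; 9 adjusted over the list alone; exact adjusted p = 0.368), including PHF20L1, BPTF, KDM6A, a histone demethylase (50% to 83.7%), and SIRT2 (40.9% to 75.4%, at 5' sites 1 nt apart). KDM6A and SIRT2 lost their calls with the correction (adjusted p of 0.492 and 0.0624), and PHF20L1 and BPTF kept theirs. The direction is not defined for BPTF and SIRT2, at competing sites.

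Cell cycle genes changed in 6 of 76 cases (4 higher, 2 lower; 6 adjusted over the list alone; exact adjusted p = 0.926), with CLASP2, CDK13 (59.2% to 30.1%), the mitotic kinesin KIF11 (80.8% to 100%) and CDC7 (17.0% to 34.8%). For apoptosis the count was 3 of 29 (2 higher, 1 lower; 3 adjusted over the list alone; exact adjusted p = 0.701), with BCLAF1, BAG4 (18.1% to 49.8%) and CYCS, cytochrome c (88.9% to 73.3%). DNA repair had 1 of 46 genes changed, TP53BP1 (92.8% to 74.7%; 1 adjusted over the list alone; exact adjusted p = 0.636). Translation had 4 of 39 (2 higher, 2 lower; 4 adjusted over the list alone; exact adjusted p = 0.636), with EIF4ENIF1, EIF4G3 (69.5% to 49.1%), EIF4G2 (86.0% to 100%) and EIF2AK4 (5% to 28.4%). Membrane trafficking had 5 of 76 genes changed, all 5 lower as counted, and 3 adjusted over the list alone (exact adjusted p = 1.00), including EXOC3 (98.1% to 72.9%), SEC16A (57.7% to 33.3%), RAB6A (95.8% to 75.6%) and TBC1D22A. The direction is not defined for EXOC3, at competing 5' sites, or for RAB6A, in a retained intron. In the ubiquitin system, 5 of 78 changed, all 5 lower as counted (5 adjusted over the list alone; exact adjusted p = 1.00), including UBE2E3, UBE4A (25.8% to 0%, which allows up to 5.88%), USP8 (43.1% to 17.8%) and RNF149 (63.2% to 40%). The direction is not defined for UBE2E3, in a retained intron, or for UBE4A, in a mutually exclusive row. Nor is it defined for CDK13, KIF11, BCLAF1, CYCS and TP53BP1, at competing sites, or for CDC7, in a retained intron. The same holds for EIF4G2 and EIF2AK4, in mutually exclusive rows. Of the genes named in this paragraph, CDK13, KIF11, BCLAF1, CYCS and EIF4G2 kept their calls with the correction, and the others lost theirs.

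Markers of other cell types had few tested events. Of 2 tested T cell marker genes and 1 tested fibroblast marker gene, 0 changed (0 adjusted over the list alone; exact adjusted p = 1.00 for each list). The 1 tested myeloid marker gene, MPEG1, changed in a mutually exclusive row (20.8% to 0%, which allows up to 1.11%; 1 adjusted over the list alone; exact adjusted p = 0.299), a call lost with the correction. The reads themselves differed between the libraries for CD3D, a T cell receptor complex gene, with 69 in wild type and 759 in the deficient library over its event with 2 numbers per library, and for VIM, the mesenchymal filament vimentin, with 347 and 49 over its deepest event. The other tested T cell marker gene, CD247, went the other way from CD3D, with 38 reads in wild type and 27 in the deficient library.

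The fourth comparison asked whether exons that fell and exons that rose differed in length and reading frame. Exons with lower inclusion in the deficient library were short, with a median of 69 nt, against 107 nt for exons with higher inclusion and 104 nt for 1343 unchanged exons. The difference from unchanged exons had an adjusted p of 0.00072 by a two-sided permutation test, and that from exons with higher inclusion 0.0230, which became 0.180 with differences of at least 20 points, where the medians were 60 nt over 29 exons and 93 nt over 35 exons. A length divisible by 3 was found in 77.8% (65.5 to 87.3) of the exons that fell, including those of PHF20L1, IMPDH2, ARHGAP17 and CLASP2, in 62.3% (49.8 to 73.7) of those that rose, and in 54.4% (51.6 to 57.0) of unchanged exons. By Fisher's exact test the exons that fell differed from unchanged exons (adjusted p = 0.00072) but not detectably from those that rose (0.0904), although the latter had 0.0147 with differences of at least 20 points. Exons that rose did not differ detectably from unchanged exons in length (0.783) or divisibility (0.259). Unchanged exons were mostly included, with a median of 96.3% in wild type. Against unchanged exons at 10% to 90% inclusion, a set chosen after seeing the data, the difference in length kept an adjusted p of 0.0199 and that in divisibility had 0.0904.

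**Figure D4:**
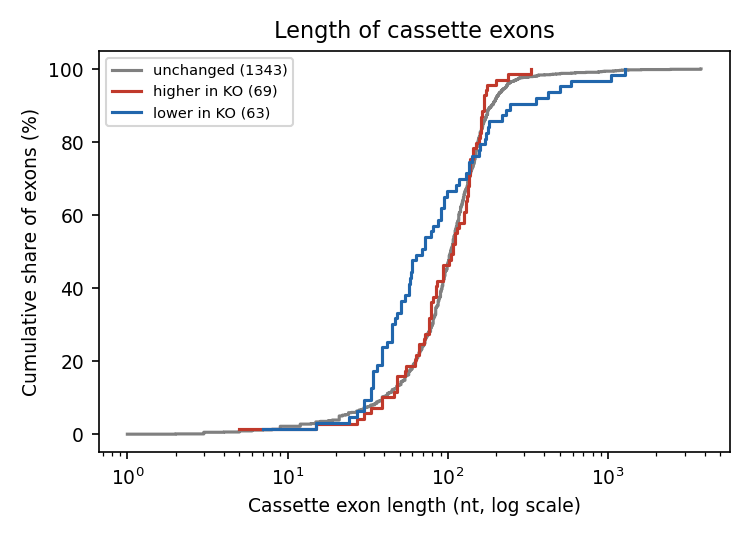
Cumulative share of cassette exons (%, y axis) by exon length (nt, logarithmic x axis) for exons unchanged (grey, 1343), higher (red, 69) and lower (blue, 63) in the SRSF10-deficient library. The curve of the exons with lower inclusion lies to the left over most short lengths, with a median of 69 nt against 107 nt and 104 nt.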

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

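Of the tests in this part, those of sequence placement, chromosome naming, read depth, spread between libraries and matched gene lists were chosen after the results they bear on had been seen. What the general shift and the matched lists would show was written down before those values were computed.

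VPS33B stood out among the rows with 3 or more numbers, which were outside the comparisons above. Its adjusted p in the authors' deposited table was 0.0118, with listed numbers of 92, 109 and 17 in wild type and 175, 287 and 112 in the deficient library. CD3D, from the T cell marker list, stood out by reads, which the splicing comparison does not use. Its event with 2 numbers per library (chromosome 24, 5482034 to 5482157) had 69 reads in wild type and 759 in the deficient library, a ratio of 11.0 (8.59 to 14.3). A row of CD3D with 3 numbers (5482845 to 5483009) listed 207, 260 and 207 in wild type and 1667 for each in the deficient library.

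Changed cassette exons such as EPRS, PTPRC, PHF20L1 and IMPDH2 differed between the libraries by far more than counting noise. A general shift of more than 1 point at the median exon, the limit set in advance, is argued against. The median difference over 2175 tested cassette exons was 0.443 points (0.267 to 0.576), a small upward shift. Median inclusion in wild type was 88.6%, and exons near full inclusion have little room to rise. The median therefore cannot exclude a shift limited to exons of intermediate inclusion. A spread between any 2 libraries above counting noise may account for many of the calls. With that spread removed at the level of the median event, 9.09% (4.79 to 15.3) of the 132 changed exons kept the call, 12 exons in all. Loss of SRSF10 stays open as the biological explanation for either group of exons, since 1 library per genotype confounds genotype with library.

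Changes of at least 50 points were listed for 25 events, including MKS1, B-G, TUBB and HNRNPA2B1. Some rest on the same reads. TUBB was listed more than once with equal counts, BCLAF1 also as LOC100858086, and SLC38A7 and BBX as mirrored rows. The tests below treat all 25 as independent. Unplaced scaffolds and chromosome 16 held 28.0% (12.1 to 49.4) of them, against 8.43% of smaller changes (Fisher's exact p = 0.00703), too few to be the whole source. Rows without the chromosome prefix made up 48.0% (27.8 to 68.7), against 11.1% of smaller changes (Fisher's exact p = 2.13e-05), and whether they are the main source cannot be told apart at 25 events. Event type was not tested as a source. Many of the 25 were mutually exclusive rows, whose spread was 13.7 times counting noise. How far these are the rows without the prefix was not tested. Low depth may contribute, since over all tested events, called or not, the median of the smaller library's reads was 29 for differences of at least 50 points and 82 for smaller ones (permutation p = 0.0496, close to the threshold). MKS1, with 254 and 249 reads, was not shallow, and loss of SRSF10 stays open for it, as untested.

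The cytoskeleton list, with ARHGAP17, SPTAN1, KLC1 and EPB41, had 12 changed genes. Genes with more events and more reads are called more often, but lists matched on both had a median of 6 changed genes, and the central 95% of them reached 11. The count of 12 lay above that range, which argues against that as the whole source, but only weakly. The one-sided p over these random lists, 0.0104, was not adjusted over the 17 lists, of which this one was picked because it stood out. The spread between libraries stays open, since with the correction for it 3.39% of the list and 1.38% of other genes changed (exact adjusted p = 0.576), too few calls to decide, and an effect of SRSF10 on these genes was not tested apart from it.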

How the results depend on the processing

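The divisions by inflation, the narrower event types, the matched lists and the intermediate unchanged exons were chosen after seeing the data. The direction of single events was compared for the 81 named events only. The median length of exons that rose, 107 nt, was not called different from unchanged exons (104 nt), and was 93 nt at 20 points. Of the 286 changed events, 156 remained with differences of at least 20 points, 108 with reads divided by 2, 148 with 1 event per gene and 56 with the division by inflation. The division left the chi-square of undefined events as it was, and 8 of their 11 calls were kept after renewed adjustment over all events. The authors' adjusted p called 172 events. For cassette exons, 69 higher and 63 lower became 35 and 29 at 20 points, 20 and 21 with reads divided by 2, 40 and 32 with 1 event per gene, 45 and 40 with inclusion reads halved, and 6 and 6 with the division by inflation. For the other types, 82 higher and 72 lower became 46 and 46 at 20 points, 37 and 30 with reads divided by 2, 44 and 32 with 1 event per gene, 22 and 20 by the authors' p, 24 and 20 with the division, and 44 and 35 in the narrower set. At a minimum of 50 reads, the count of lower events of other types was 47. The cytoskeleton list had an adjusted p of 0.0948 with cassette exons alone, 0.165 at 20 points and 0.576 with the division, against 0.0108, and 0.0233 at 50 reads. Divisibility by 3 of exons that fell had 0.0904 against intermediate exons. At 20 points, the lengths of exons that fell and rose differed with an adjusted p of 0.180, and their divisibility with 0.0147. Settings with higher thresholds or fewer events have fewer calls by construction, and otherwise the cause was not tested. Of 81 named events, 68 kept the call with cassette inclusion halved, 44 with reads divided by 2, 26 with the division and 35 by the authors' p, and 0 changed sign. These settings leave the sign of a difference nearly fixed, so the last count does not test direction. Purine-rich motif alternatives were not run, and with 1 library per genotype no library could be left out. Depth limits the results at small changes, since 44.5% of simulated 15-point changes were recovered.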

Other observations

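The tests on exons of the same gene and on nearby splice sites were chosen after the results had been seen.

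Reads over a gene's deepest event give a rough view of expression, with no library totals to scale them and no replicate. Among listed genes, the B-cell signalling kinase PRKCD had 3 reads in wild type and 57 in the deficient library, a ratio of 19.0 with a counting interval of 6.18 to 94.9. SPTBN1, a spectrin, had 8 and 97 reads (12.1, 5.91 to 28.9), and the kinesin KIF2A had 1 and 130 reads (130, 22.9 to 5174). VIM had 347 and 49 reads, a ratio of wild type to deficient of 7.08 (5.24 to 9.76), and ENAH, an actin regulator, had 39 and 9 (4.33, 2.06 to 10.2). Further lymphocyte genes, named after their values were seen, were BTLA, an inhibitory receptor, with 95 and 1004 reads (10.6, 8.56 to 13.2), and the transcription factor IRF8, with 2569 and 759 (3.38, 3.12 to 3.68). Of 3642 genes, 48 had at least 4 times the reads in the deficient library and 39 at least 4 times the reads in wild type. As a description of these libraries, the median log2 ratio was 0.16 for chromatin regulators, at the 98.6th percentile of random lists matched on reads, and 0.15 for B-cell signalling genes, at the 95.7th percentile. These lists are given because they had the highest percentiles of all lists compared, and the percentiles were not adjusted over the lists.

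A hypothesis is that changed cassette exons of the same gene may move together. In ARHGAP17, 3 exons fell (60.4% to 17.1%, 53.8% to 25% and 20.4% to 5.22%), in BBX 2 exons fell, in MEAF6 2 exons fell, and in PHF20 2 exons rose (45.8% to 66.3% and 53.0% to 73.4%). Only cassette exons were counted. A changed PHF20 event with no defined type (chromosome 20, 906237 to 906515) went the other way, from 90.8% to 72.4%. With exons that do not overlap, 5 of 5 genes had 1 direction (one-sided permutation p = 0.0173). That set held ZNF217, whose exons share their exclusion reads, and a stricter definition without such exons, adopted after that result, gave 4 of 4 genes (permutation p = 0.0300). With so few genes, and with exons that can be joined in 1 transcript, this remains a hypothesis.

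Alternative sites at most 10 nt apart changed in 24 of 437 tested events, as in SRSF6, CTSB and SIRT2, and 1 of the 437 had an adjusted p under 0.05 in the authors' deposited table. Sites farther apart changed in 59 of 1445, and 25 had such a p. An authors' adjusted p of 1 was listed for 90.2% of the near and 56.7% of the far sites. A count of 0 in any cell was found in 9 of the 24 near and 25 of the 59 far changed events (Fisher's exact p = 0.807), and 2 of the 24 lay in ribosomal protein genes.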
